A study of Homo sapiens with 28 samples.

How the data were processed

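RNA from MCF-7 cells, an established estrogen receptor positive human breast cancer line, was measured on 28 one-colour Agilent whole-genome arrays, 1 array per sample. Cells were kept for 24 h with estradiol at 1 nM, arsenite at 1 µM, cadmium at 1 µM or none of these, each without or with the antiestrogen fulvestrant at 500 nM, which the labels give by its ICI code and which is written ICI here. The 8 groups held 4 arrays each without ICI and 3 arrays each with it. The labels number the replicates but do not say whether these were separate cultures, so the replicate error may be technical.

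Per the file headers, the scanner files were made with Agilent Feature Extraction 11.5.1.1, which gives for every spot a processed intensity after background subtraction and spatial detrending within the array, raw median intensity of the spot and of its local background, and other columns that hold the software's 0 or 1 calls of spot quality. The values deposited by the authors in the series table are the same processed intensity rounded to 3 significant digits; the largest log2 difference from the scanner files was 0.0072. No scaling between arrays had been applied, since the medians of the deposited columns ran from 29.4 to 101. The array grid was drawn for the hg19 build, and no coordinates are given here.

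The arrays held 42405 probes other than controls, on 58717 spots. The files give probe names and accessions but no gene symbols, so symbols were taken from a RefSeq gene table by matching accessions; 26910 probes (63.5%) matched 20108 symbols, among them 26890 of the 27639 probes with a RefSeq accession. The other 15495 probes, most of them for long non-coding or unannotated transcripts, stayed without a symbol and were tested but not named.

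For each array, spots that the scanner software marked as non-uniform or as outliers were left out, spots of the same probe were averaged, and log2 of the processed signal was taken minus the array's 75th percentile of that value over all probes other than controls. A probe was kept if it was well above background on every array of at least 1 group, which left 29717 probes and removed 12688 dim ones. Each gene was then represented by its brightest remaining probe, which gave 24322 genes, 15426 of them with a symbol; a probe without a symbol counted as a gene of its own.

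Group means were fitted to all 28 arrays with limma 3.58.1 (lmFit and eBayes, moderated tests, two-sided) in R 4.3.3, with no covariates. The fit had 20 residual degrees of freedom, a prior of 1.53 degrees of freedom and a median residual SD of 0.158 on the log2 scale. The 16 contrasts were each compound against control, ICI against control, each compound with ICI against ICI alone, each compound with ICI against the same compound without it, the 3 interactions of a compound with ICI, and the 3 pairs of compounds. The interaction is the compound's log2 change in the presence of ICI minus its change in the absence of ICI. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Errors after ± are standard errors of the log2 change from this fit unless another error is named.

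Where a group was not above background on any of its arrays, the fold change is a lower bound, taken against the dimmest spot that the software still called well above background on those arrays, and is written as "at least". The genes named in the text follow a rule written before the data were examined: in each comparison, the 10 largest rises and 10 largest falls among called genes with a symbol in which all arrays of one group lay above all arrays of the other (this condition was dropped for interactions), of which the text gives a part; the 2 to 4 members with the smallest p in each gene list described; the 5 genes per direction with the largest product of the estradiol and metal changes; and a panel of GREB1, PGR, TFF1, PDZK1, CXCL12, MT1X, MT2A, HMOX1, ESR1 and MKI67. With 4 against 4 arrays, chance alone gives no overlap, in either direction, in 1 of 35 splits.

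The 20 gene lists were also fixed beforehand: estrogen-induced genes, estrogen-repressed genes, DNA replication and G1/S genes, mitosis genes, metallothioneins and zinc efflux, zinc and metal transporters, NRF2 and oxidative stress genes, heat shock genes, ATF4 and unfolded protein response genes, p53 targets, sterol synthesis genes, hypoxia and glycolysis genes, interferon response genes, aryl hydrocarbon receptor genes, ribosome biogenesis and MYC genes, luminal breast epithelium markers, basal and mesenchymal cell markers, immune cell markers, inflammatory and immediate early genes, and apoptosis regulators. Each list was tested against all other genes with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 320 tests of 20 lists in 16 contrasts, and again with the correlation estimated from the data. A list is said to rise or fall only where the first of these tests passed, and its p with the estimated correlation is printed where that p did not pass. ALDH3B2, AKR1C2, ALDOA, IFI27, AHRR and LYZ were on the lists but had no probe matched to them.

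The likeness of a metal to estradiol was measured in 3 ways. The aligned change is the mean log2 change with the metal over the genes called for estradiol, with its sign turned for genes that estradiol lowered; estradiol and the metal were set against different control arrays, in each of the 6 ways to divide the 4 controls. The covariance of the fold changes over all genes was taken with the same controls, minus its mean over 20 simulations in which no group was changed. The number of genes called in the same direction was set beside the number that independent calls would give, which leaves out the shared controls, beside its mean over simulations of unchanged groups, and beside its mean over the ways to divide the controls.

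Slide and scan day were read from the file headers. Controls and estradiol lay on slide 1, arsenite and cadmium on slide 2, ICI alone with 1 array of estradiol with ICI on slide 3, and the remaining 8 arrays on slide 4; slides 1 and 2 were scanned on one day and slides 3 and 4 on another. Estradiol against control and arsenite against cadmium are therefore comparisons within a slide, and the other comparisons of groups are not. On slides 1 and 2 each group filled a row of its own, so row and treatment cannot be told apart in these comparisons. The alternatives tried were quantile normalization; normexp background correction (offset 50, on median signal) followed by quantile normalization; the series table in place of the scanner files; no filter on dim probes; all probes in place of 1 per gene; only the arrays of the comparison; the replicate number as a block; slide as a fixed block where it could be fitted and as a random block elsewhere; scan day as a block; a minimum of 1.5-fold; leaving out each array in turn; and the estimated correlation for gene lists. For scan day no term was fitted, and its block was a fit to the arrays of 1 day alone. A 75th percentile over the 20442 probes well above background on all arrays was added after seeing the data.

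The steps were tested on simulated data with 200 of 24303 genes changed. For estradiol against control, 74.6%, 80.6% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 13 false calls. Interactions gave 29.9% to 38.8% at 1.5-fold and 55.2% to 59.7% at 2-fold. The aligned change was estimated as 0.955 where it was 1 and as -0.004 for an unchanged metal. Figures used matplotlib 3.10.9 in Python 3.11.15. Arrays give no counts, and their number limits the precision of each value.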

Results

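The series is titled as a study of estrogen-like effects of arsenite and cadmium, and its arrays compare the metals with estradiol in MCF-7 cells, whose growth depends on the estrogen receptor ESR1. Control, estradiol, arsenite and cadmium groups held 4 arrays each, and the same 4 conditions with ICI, an antagonist that also removes the receptor protein, held 3 arrays each. The 75th percentile of the signal ran from 354 units in estradiol with ICI replicate 1 to 1281 in cadmium replicate 4, and 55.1% to 72.7% of spots were well above background. No spot was saturated. Across genes, arrays of one group correlated at r of 0.9828 to 0.9977, except in estradiol with ICI, where replicate 1 had r of 0.9452 and 0.9451 with the other arrays, which had 0.9968 with each other. Genes are not independent replicates, so these r values describe the arrays only. Replicate 1 of that group also lay on another slide than the other arrays, and its replicate probes varied by 46.7% (CV). The first principal components held 44.5%, 20.7% and 10.2% of the variance.

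Slide and group overlap in most comparisons. A fit with slide as a random block had a correlation within slides of 0.814, which rests on the single group that lay on more than 1 slide, estradiol with ICI; counts from that fit are given beside the counts they alter. ICI was given at 500 times the molar dose of estradiol, and estradiol at a lower dose than the metals, so differences in size between treatments are differences between these doses. Gene lists were tested against all genes, and where probes with no symbol moved together a list near 0 can be called in the other direction. These probes had medians of -0.7 for cadmium against control, -0.54 for cadmium against estradiol and 0.57 for arsenite against cadmium, with 0.03, -0.03 and 0 for RefSeq coding genes. Gene lists are given with their count over all genes tested and, in the first comparisons and wherever it matters, adjusted over the list alone; where the latter is not given it was the same or differed by 1 or 2 genes.

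**Figure D1:**
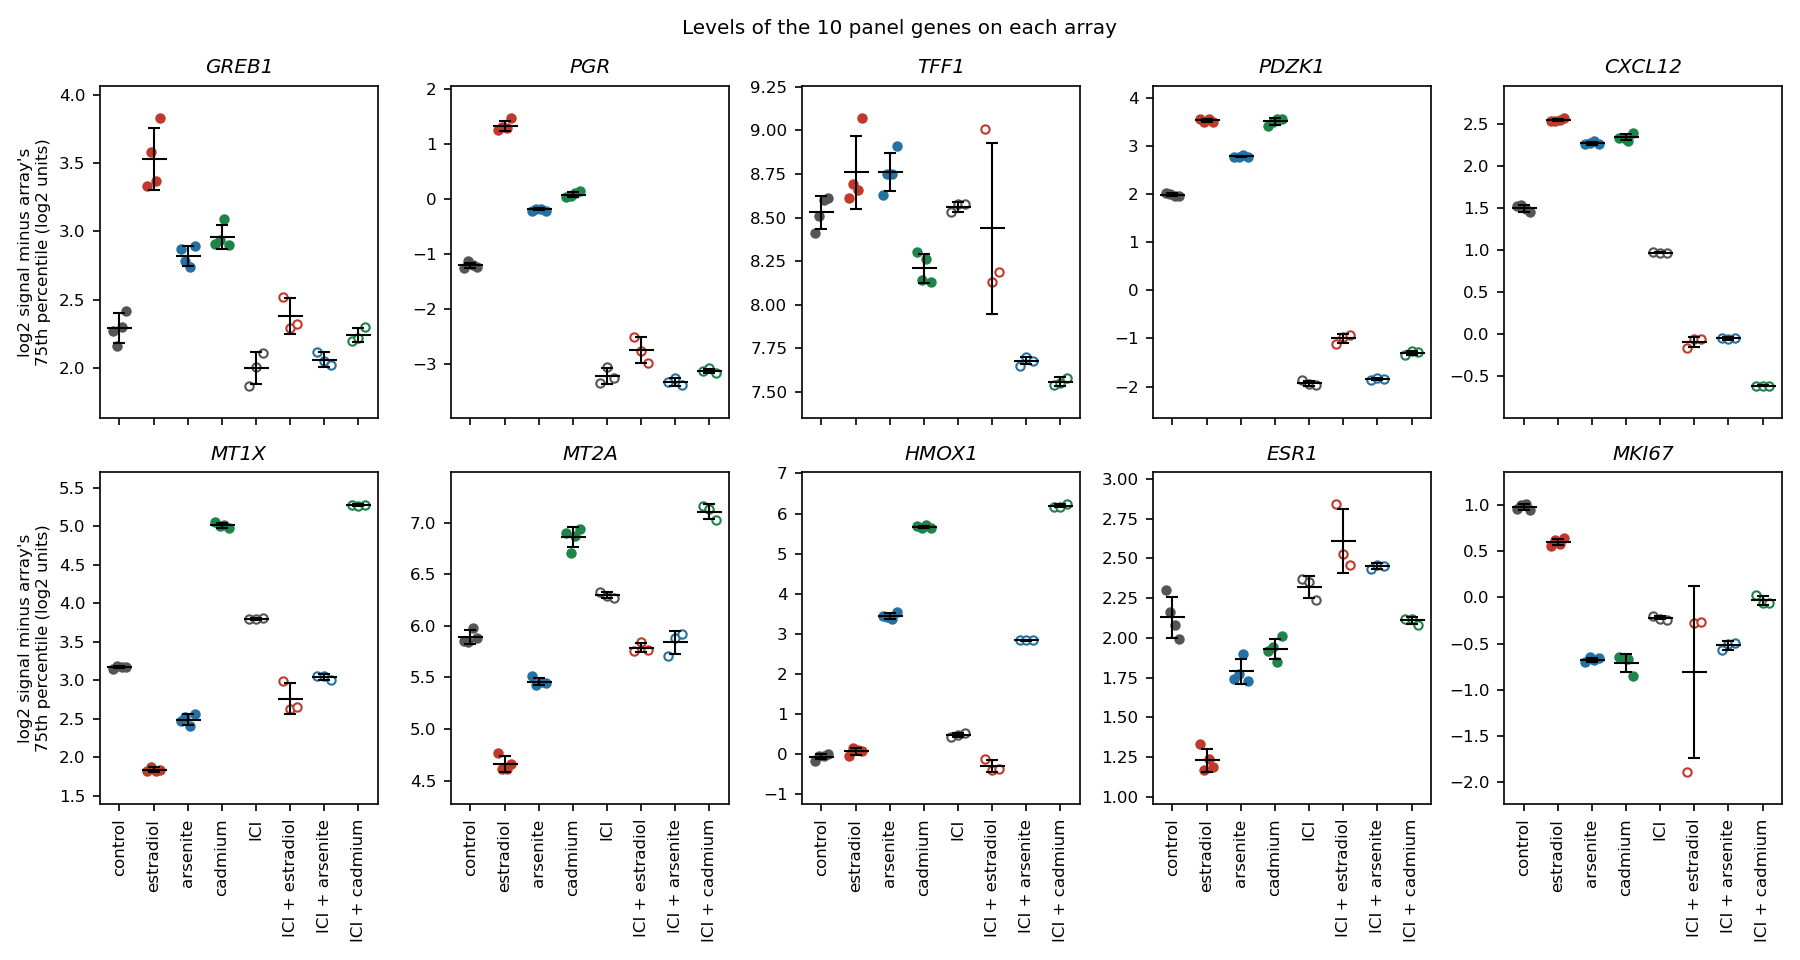
Levels of the 10 panel genes, as log2 signal minus the array's 75th percentile (y axis), in the 8 groups (x axis). Each dot is an array, filled without ICI and open with it, and bars give the mean ± SD of 4 or 3 arrays; mean PGR was -1.21 in controls, 1.33 with estradiol, -0.19 with arsenite, 0.08 with cadmium and -3.22 with ICI alone.

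Estradiol was compared with control to give the reference response. PGR, the progesterone receptor and a direct target of the estrogen receptor, rose 5.8-fold (2.54 ± 0.074, n = 4 and 4, adjusted p = 1.9e-17), PDZK1, a scaffold protein, 2.93-fold (1.55 ± 0.041, 6.2e-18), GREB1, a cofactor of the receptor, 2.36-fold (1.24 ± 0.087, 4.9e-11) and the chemokine CXCL12 2.07-fold (1.05 ± 0.03). TFF1 was already among the brightest signals in controls, and its change of 0.22 ± 0.13 did not pass (adjusted p = 0.15); after quantile normalization it was 0.48 and passed. The largest rises included the transcription factors SOX3 (11.6-fold) and EGR3 (9.91-fold), the adenosine receptor ADORA1 (8.62-fold), FGFBP2 (9.54-fold) and TMPRSS3 (8.55-fold), and ARHGAP36, which was below background in controls, rose at least 5.67-fold. The largest falls included FAM177B (37.1-fold), the non-coding RNA DRAIC (10.9-fold), CGA, which encodes the alpha subunit of glycoprotein hormones (9.61-fold), PIP (7.21-fold) and TM4SF1 (6.84-fold). ESR1 itself fell 1.87-fold (-0.9 ± 0.071), although its probes ranged from -0.9 to 0.1. MT1X and MT2A, metal-binding metallothioneins, fell 2.51-fold and 2.34-fold. HMOX1 was 0.14 ± 0.056 (adjusted p = 0.043), with adjusted p of 0.059 to 0.15 without control replicate 1, 2 or 3 or estradiol replicate 2, 3 or 4.

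Of 50 estrogen-induced genes measured, 41 were higher and 3 lower (42 and 3 adjusted over the list alone), with a median of 0.76 (adjusted p = 5.3e-15); FHL2 rose by 1.15 ± 0.038. Of 24 estrogen-repressed genes, 17 were lower and 5 higher (the same numbers adjusted over the list alone; adjusted p = 0.0042), among them ERBB2 (-0.91 ± 0.045) and BCAS1 (-1.48 ± 0.068); with an estimated correlation the adjusted p was 0.16. Luminal markers fell, 15 of 17 (16 adjusted over the list alone; adjusted p = 2.4e-06), including GATA3 (-0.72 ± 0.044), KRT8 (-1.26 ± 0.075) and TFAP2C (-0.89 ± 0.029). Cell-cycle genes went different ways. Mitosis genes fell, 20 of 33 with 3 higher (20 and 3 adjusted over the list alone; median -0.53, adjusted p = 5.3e-06), among them PLK1 (-1.21 ± 0.065), HMMR (-1.01 ± 0.05) and NDC80 (-0.62 ± 0.025). Replication genes rose, 16 of 35 with 3 lower (16 and 3 adjusted over the list alone; median 0.2, adjusted p = 0.015), among them FEN1 (1.11 ± 0.052) and PRIM1 (0.43 ± 0.029). Their adjusted p was 0.34 with an estimated correlation. MKI67, a proliferation marker, was -0.38 ± 0.2 (adjusted p = 0.13), with levels of 0.95 to 1.01 in controls and 0.56 to 0.64 with estradiol. Its SE is pooled over all 8 groups. Its SD was 0.93 in estradiol with ICI, where replicate 1 was at -1.89, against 0.018 to 0.099 in the others. For TFF1 these SDs were 0.49 and 0.022 to 0.21. A call missing for MKI67 or TFF1 is thus not evidence of no change. Ribosome biogenesis genes rose, 18 of 26 with 6 lower (18 and 6 adjusted over the list alone; adjusted p = 0.00015), led by RRP12 (1.08 ± 0.042) and PPAN (1.26 ± 0.062). So did ATF4 targets, 14 of 24 (14 adjusted over the list alone; adjusted p = 0.00027), led by DDIT3 (1.63 ± 0.052), and p53 targets, 13 of 22 (14 adjusted over the list alone; adjusted p = 0.0015), including CDKN1A, an inhibitor of cyclin-dependent kinases (1.29 ± 0.096), and AEN (1.44 ± 0.074). With an estimated correlation the adjusted p was 0.31, 0.19 and 0.085 in that order. The metallothionein list fell, 8 of 10 with 1 higher (8 and 1 adjusted over the list alone; median -1.18, adjusted p = 0.00028; adjusted p = 0.079 with an estimated correlation).

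In all, 13227 of 24322 genes (54.4%) were called for estradiol, 6184 higher and 7043 lower, of which 919 and 1183 changed at least 2-fold. Controls and estradiol shared a slide but lay in different rows of it. For genes that changed at least 2-fold and had another probe, the other probes gave 0.71 of the rise and 0.27 of the fall, on arrays not used to choose the genes. When genes were chosen by their other probes instead, on all arrays, the probe used gave 0.22 of the rise and 0.37 of the fall. The fall of BASP1 (-3.01 ± 1.1) rested on estradiol replicate 4, without which it was -1.29 (adjusted p = 0.095), and ADAM11 fell by 3.88 with the probe used but another probe of the gene gave 0.65.

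**Figure D2:**
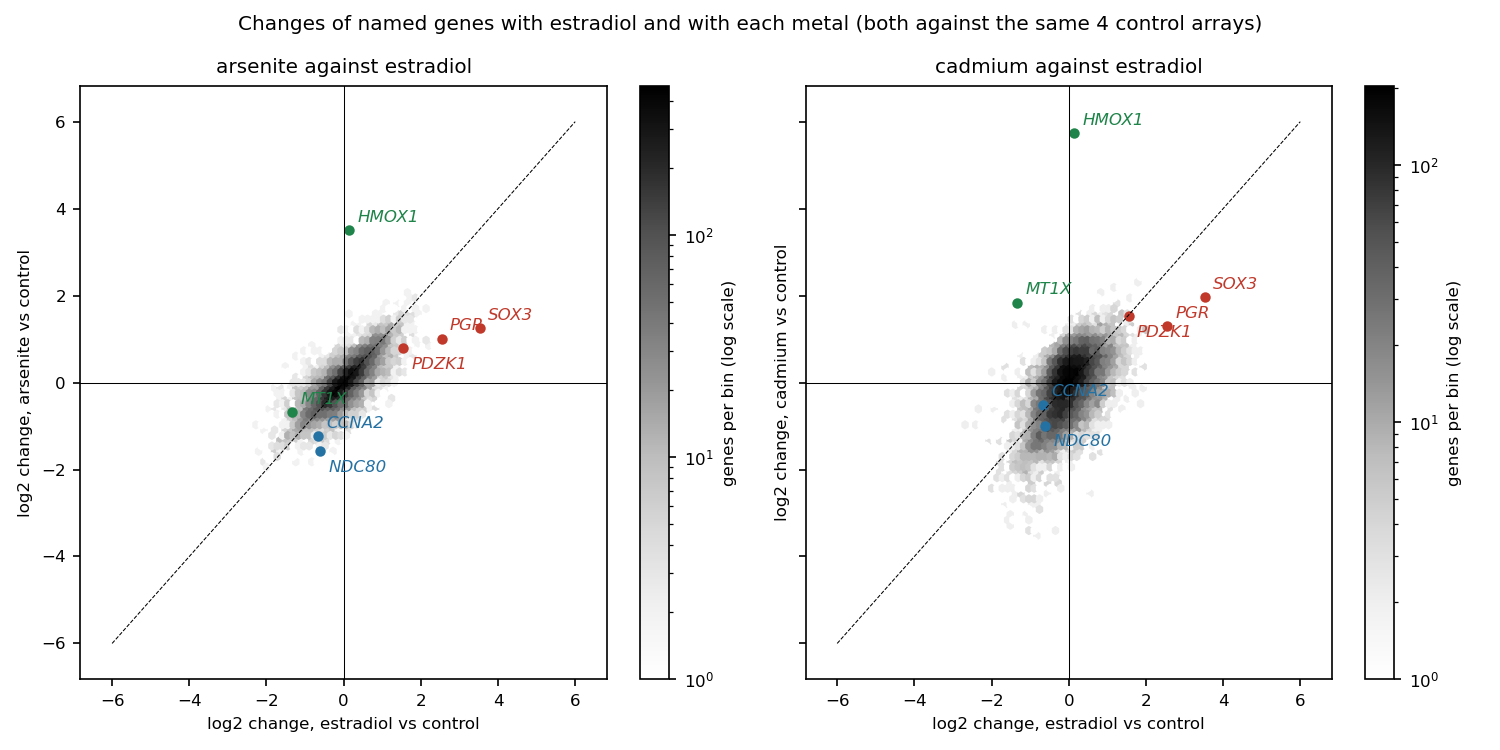
Log2 change with arsenite and with cadmium (y axes) against log2 change with estradiol (x axes), each versus the same 4 control arrays, over genes with a symbol; darker hexagons hold more genes and the dashed line marks equal changes. PGR, PDZK1 and SOX3 (red) lie to the right, HMOX1 and MT1X (green) apart from the line, and CCNA2 and NDC80 (blue) below 0. The shared controls raise the correlation. Over all genes tested, with or without a symbol, it was 0.786 and 0.616 in the data. Simulations in which no group was changed, estradiol included, gave 0.499 and 0.501, which is not what an unchanged metal would give here.

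Arsenite was compared with control to ask whether it acted as estradiol did. It raised PGR 2.02-fold (1.01 ± 0.074, n = 4 and 4, adjusted p = 1e-10), PDZK1 1.74-fold (0.8 ± 0.041), CXCL12 1.71-fold (0.77 ± 0.03) and GREB1 1.45-fold (0.53 ± 0.087, 2e-05), and TFF1 was 0.23 ± 0.13 (adjusted p = 0.15; 0.43 and passing after quantile normalization). Among stress genes, HMOX1, which encodes heme oxygenase, rose 11.4-fold (3.51 ± 0.056, 9.4e-22), and the aldo-keto reductases AKR1C3 and AKR1C1 rose 5.7-fold and 4.49-fold. The ribosomal RNA gene RNA5-8SN5 rose 24.3-fold and the small nucleolar RNA SNORD15A 4.82-fold. FAM177B fell 30.8-fold, as it had with estradiol, ANK2 5.72-fold and CNIH2 at least 4.99-fold. MKI67 fell 3.15-fold (-1.65 ± 0.2, 4.5e-07). The metallothioneins MT1X and MT2A fell 1.6-fold and 1.34-fold, and ESR1 fell 1.27-fold, with another of its probes at 0.98.

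Estrogen-induced genes rose with arsenite, 30 of 50 with 5 lower (32 and 5 adjusted over the list alone; median 0.32, adjusted p = 1.1e-06), among them TPD52L1 (0.76 ± 0.031), CA12 (0.6 ± 0.028) and CCND1, which encodes cyclin D1 (0.86 ± 0.041). Estrogen-repressed genes did not pass (9 higher, 11 lower, adjusted p = 0.79). NRF2 genes rose, 18 of 27 with 5 lower (18 and 5 adjusted over the list alone; median 0.66, adjusted p = 2e-06), including G6PD, which supplies NADPH (1.71 ± 0.033), and SQSTM1 (1.02 ± 0.032). Mitosis genes fell, 30 of 33 (31 lower and 1 higher adjusted over the list alone; median -1.23, adjusted p = 7.5e-20), with NDC80 at -1.57 ± 0.025 and CENPF at -1.81 ± 0.044. Replication genes fell too, 22 of 35 with 2 higher (22 and 2 adjusted over the list alone; adjusted p = 7e-06), with CCNE2 at -1.45 ± 0.064 and CCNA2 at -1.23 ± 0.048. Their adjusted p was 0.076 with an estimated correlation. The p53 targets rose, 15 of 22 (adjusted p = 0.001), led by CDKN1A (1.68 ± 0.096). So did ATF4 targets, 12 of 24 (adjusted p = 0.0076), led by DDIT3 (1.5 ± 0.052), inflammatory genes, 11 of 19 (adjusted p = 0.044), with EGR1 at 0.97 ± 0.051, and ribosome biogenesis genes, 17 of 26 (adjusted p = 0.0015), with RRP12 at 1.11 ± 0.042. For these 4 lists the adjusted p was 0.079, 0.34, 0.078 and 0.39 with an estimated correlation. Metallothioneins (7 of 10 lower, adjusted p = 0.018), interferon genes (12 of 22 lower, adjusted p = 0.0046) and luminal markers (11 of 17 lower, adjusted p = 0.014) fell, and with an estimated correlation the adjusted p was 0.26, 0.25 and 0.15. SLC30A1, a zinc exporter on the metallothionein list, rose by 0.7 ± 0.094. The luminal call was also lost after quantile normalization (adjusted p = 0.095).

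For arsenite, 12942 genes (53.2%) were called, 6066 higher and 6876 lower, of which 917 and 837 changed at least 2-fold. Arsenite lay on another slide than the controls, and with slide as a random block 1540 genes were called.

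Cadmium was compared with control for the same question. HMOX1 rose 53.2-fold (5.73 ± 0.056, n = 4 and 4, adjusted p = 1.4e-26), AKR1C3 19.3-fold and AKR1C1 11.6-fold, the cytokine IL24 7.3-fold and ADORA1 6.26-fold. MT1X and MT2A rose 3.59-fold and 1.95-fold (1.84 ± 0.054 and 0.97 ± 0.053), opposite to their change with estradiol and arsenite. Among estrogen-responsive genes, PDZK1 rose 2.89-fold (1.53 ± 0.041, 1.3e-18), PGR 2.44-fold (1.29 ± 0.074), CXCL12 1.79-fold (another probe of it was -1.04) and GREB1 1.59-fold, and TFF1 fell by 0.33 ± 0.13 (adjusted p = 0.029), a direction that turned under quantile normalization (0.48) and a call lost without cadmium replicate 2 or 4 or control replicate 3 or 4 (adjusted p = 0.063 to 0.068). MKI67 fell 3.22-fold (-1.69 ± 0.2, 1.8e-07). The histone gene H3C15 fell 45.2-fold, C3AR1 38.2-fold, the splicing factor TRA2A 27.6-fold and FAM177B 26-fold, and IRGQ fell at least 14.3-fold.

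Estrogen-induced genes rose with cadmium, 32 of 50 with 9 lower (32 and 9 adjusted over the list alone; median 0.43, adjusted p = 9.9e-08), among them TPD52L1 (1.29 ± 0.031) and NPY1R (1.49 ± 0.063). NRF2 genes rose, 19 of 27 with 4 lower (19 and 4 adjusted over the list alone; median 0.79, adjusted p = 1e-07), with G6PD at 1.97 ± 0.033 and ME1 at 1.95 ± 0.042. The metallothionein list rose, 8 of 10 with 1 lower (8 and 1 adjusted over the list alone; median 1.28, adjusted p = 0.00017; adjusted p = 0.076 with an estimated correlation), with MT1F at 1.31 ± 0.076 and MT1L at 1.29 ± 0.051. Mitosis genes fell, 25 of 33 with 1 higher (25 and 1 adjusted over the list alone; median -0.72, adjusted p = 1.1e-05), with CENPF at -1.84 ± 0.044 and PLK1 at -1.86 ± 0.065. Replication genes were 13 higher and 13 lower (adjusted p = 0.54). The p53 targets rose, 17 of 22 with 1 lower (18 and 1 adjusted over the list alone; adjusted p = 9.1e-07), with FAS, a death receptor, at 1.45 ± 0.044 and MDM2, which targets p53 for degradation, at 1.19 ± 0.044. ATF4 targets (16 of 24 higher, adjusted p = 0.00015), heat shock genes (11 of 20 higher, adjusted p = 0.033), inflammatory genes (11 of 19 higher, adjusted p = 0.025) and ribosome biogenesis genes (16 of 26 higher, adjusted p = 0.00072) rose as well, and with an estimated correlation the adjusted p was 0.17, 0.44, 0.054 and 0.36. Members of these lists differed: DDIT3 rose by 1.34 ± 0.052 and AHSA1 by 1.07 ± 0.062, while the chaperones PDIA4 (-3.0 ± 0.043) and HSPA1B (-1.31 ± 0.051) fell. Estrogen-repressed genes (adjusted p = 0.98), luminal markers (12 of 17 lower, adjusted p = 0.057) and zinc and metal transporters (adjusted p = 0.54) did not pass. Single members of them moved: TFAP2C was -3.84 ± 0.029, SLC39A9 was -1.91 ± 0.077 and the transferrin receptor TFRC rose by 1.73 ± 0.04.

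For cadmium, 17227 genes (70.8%) were called, 6547 higher and 10680 lower, of which 749 and 4561 changed at least 2-fold. The excess of lower genes lay in probes with no symbol, whose median was -0.7, against 0.03 for RefSeq coding genes (5324 higher and 4784 lower); quantile normalization gave 8114 and 7219. With slide as a random block 4597 genes were called.

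Likeness to estradiol was then measured over genes with or without a symbol. Genes called for estradiol moved in its direction by a mean of 0.486 log2 units with arsenite (0.473 to 0.504 over the 6 ways to divide the controls; SD 0.009, n = 4 arrays) and 0.601 with cadmium (0.578 to 0.623; SD 0.021, n = 4). With all 4 controls shared the values were 0.481 and 0.598. Simulated groups with no change at all, estradiol included, gave 0.204 over genes chosen at p under 0.05 before adjustment. That value is therefore at an unlike threshold and is not what an unchanged metal would give here. The covariance of the fold changes, beyond that of unchanged groups, was 0.238 for arsenite and 0.295 for cadmium. After normexp and quantile normalization it was 0.109 and 0.135, and the aligned changes were 0.392 and 0.469. Of the genes called for both estradiol and arsenite, 9667 changed in the same direction, 4541 up and 5126 down, and 479 in opposite directions. For cadmium these were 8975 (3751 up and 5224 down) and 1770. Independent calls, which leave out the shared controls, would give 1542 up and 1991 down for arsenite and 1665 and 3093 for cadmium. With divided controls the means were 3793 up, 4021 down and 359 opposite for arsenite and 3198 up, 4365 down and 1396 opposite for cadmium, and with unchanged groups, at p before adjustment, 251.1 and 257 genes in all. FAM177B, ADORA1, IL24 and EGR3 were among the genes with the largest shared changes; IL24 rose by 2.85 ± 0.056 with estradiol and by 2.87 ± 0.056 with cadmium, and EGR3 by 2.46 ± 0.16 with cadmium. With slide as a random block, 1467 arsenite genes and 3738 cadmium genes were shared with estradiol.

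**Figure D3:**
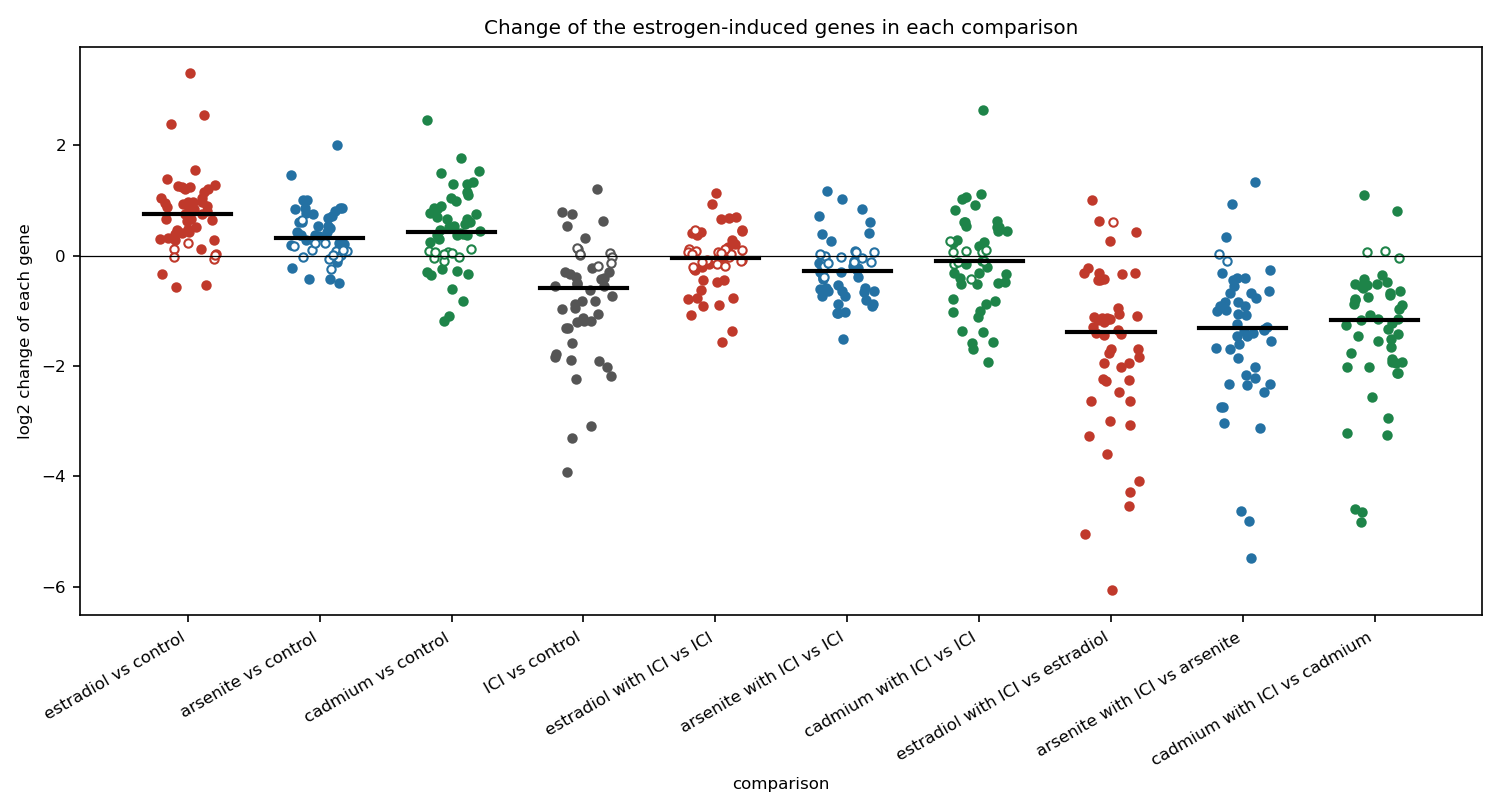
Log2 change of the 50 estrogen-induced genes (y axis) in 10 comparisons (x axis); each dot is a gene, filled where its adjusted p was under 0.05, and bars are medians. The median was 0.76 with estradiol, 0.32 with arsenite, 0.43 with cadmium and -0.59 with ICI alone, and between -1.38 and -1.16 where ICI was added to a compound.

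Arsenite was compared with estradiol directly. HMOX1 was 10.3-fold higher with arsenite (3.37 ± 0.056), SHISA2 6.39-fold, PIP 5.64-fold, DRAIC 5.39-fold and CGA 5.03-fold, the last 3 being genes that estradiol had lowered. PGR was 2.88-fold lower (-1.52 ± 0.074), PDZK1 1.69-fold, GREB1 1.63-fold and SOX3 4.87-fold, and UGT2B15, which conjugates steroids, 4.71-fold. Estrogen-induced genes were lower with arsenite than with estradiol, 28 of 50 with 5 higher (29 and 5 adjusted over the list alone; median -0.39, adjusted p = 2.5e-11), led by MYBL1 (-1.66 ± 0.074). Estrogen-repressed genes were higher, 15 of 24 with 2 lower (16 and 2 adjusted over the list alone; adjusted p = 2.9e-07), with BCAS1 at 1.09 ± 0.068. Mitosis genes (30 of 33 lower, adjusted p = 1.2e-27), replication genes (30 of 35 lower, adjusted p = 2.2e-23) and interferon genes (17 of 22 lower, adjusted p = 4.7e-10) were lower with arsenite; adjusted over the list alone, 30, 31 and 18 were lower. NRF2 genes (17 of 27 higher, adjusted p = 9.4e-11), luminal markers (10 of 17, adjusted p = 1.4e-05) and metallothioneins (7 of 10, adjusted p = 8.5e-06) were higher, as were aryl hydrocarbon receptor genes (4 of 7 higher, adjusted p = 0.008; adjusted p = 0.078 with an estimated correlation), with UGT1A6 at 1.7 ± 0.071. ATF4 targets (11 of 24 lower, adjusted p = 0.0075) and ribosome biogenesis genes (8 of 26 lower, adjusted p = 0.024) were lower, and with an estimated correlation the adjusted p was 0.34 and 0.56. In this comparison 7078 genes (29.1%) were called, 3845 higher and 3233 lower, and 303 with slide as a random block and 4541 after normexp and quantile normalization.

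Cadmium was likewise compared with estradiol. HMOX1 was 48.4-fold higher with cadmium, MT1X 9-fold (3.17 ± 0.054), SHISA2 8.79-fold, AKR1C3 7.81-fold and MT2A 4.57-fold. PGR was 2.37-fold lower (-1.25 ± 0.074) and GREB1 was -0.57 ± 0.087, while PDZK1 differed by -0.02 ± 0.041 (adjusted p = 0.7). C3AR1 was 19.3-fold lower, TMEM95 16-fold and RNA5-8SN5 14.1-fold. Metallothioneins were higher, 8 of 10 with 2 lower (median 2.32, adjusted p = 9.6e-08), with MT1F at 2.45 ± 0.076. NRF2 genes were higher, 18 of 27 with 3 lower (18 and 4 adjusted over the list alone; adjusted p = 4e-10), with ME1 at 1.81 ± 0.042. Estrogen-induced genes did not pass (9 higher, 27 lower, median -0.23, adjusted p = 0.21), although quantile normalization gave adjusted p = 0.0015. Estrogen-repressed genes (13 of 24 higher, adjusted p = 0.00023), p53 targets (14 of 22 higher, adjusted p = 0.0014) and hypoxia and glycolysis genes (13 of 21 higher, adjusted p = 0.0003) were higher, and with an estimated correlation the adjusted p was 0.078, 0.084 and 0.11. Heat shock genes (10 of 20 higher), aryl hydrocarbon receptor genes (4 of 7), luminal markers (8 of 17), sterol synthesis genes (9 of 21) and zinc and metal transporters (10 of 23) passed at adjusted p = 0.032, 0.01, 0.031, 0.036 and 0.033, and interferon genes (14 of 22 lower) at adjusted p = 0.013; with an estimated correlation the adjusted p was 0.43, 0.084, 0.2, 0.19, 0.069 and 0.32. Quantile normalization ended the calls of heat shock genes, luminal markers, sterol genes and transporters (adjusted p = 0.063, 0.052, 0.28 and 0.13). The 15869 genes called (65.2%) were 5357 higher and 10512 lower, against 6483 and 6105 after quantile normalization, and 2639 with slide as a random block and 10367 after normexp and quantile normalization. Other probes of genes at least 2-fold higher gave 0.2 of the rise. TFF1 was -0.55 ± 0.13 here and 0 after quantile normalization.

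Arsenite was compared with cadmium within a slide, on which the 2 groups lay in different rows. RNA5-8SN5 was 39.1-fold higher with arsenite, C3AR1 26.9-fold and the small nuclear RNA RN7SK 14-fold, and MT1X was 5.74-fold lower (-2.52 ± 0.054) and HMOX1 4.68-fold lower (-2.23 ± 0.056). PDZK1 was 1.66-fold lower with arsenite and PGR was -0.28 ± 0.074 (adjusted p = 0.0024), while GREB1 (-0.14, adjusted p = 0.18), CXCL12 (-0.06, adjusted p = 0.081) and MKI67 (0.03, adjusted p = 0.9) did not pass; TFF1 was 0.55 ± 0.13 and -0.05 after quantile normalization. Metallothioneins (8 of 10 lower, 1 higher; median -1.74, adjusted p = 9.6e-07), mitosis genes (25 of 33 lower, 1 higher; median -0.48, adjusted p = 5.1e-10) and replication genes (18 of 35 lower, 2 higher; adjusted p = 2.7e-07) were lower with arsenite, with MT1F at -1.78 ± 0.076, CDK1 at -0.96 ± 0.055 and PRIM1 at -0.61 ± 0.029. NRF2 genes were lower, 17 of 27 with 7 higher (adjusted p = 0.00014; adjusted p = 0.084 with an estimated correlation), with ME1 at -1.26 ± 0.042. Weaker calls for p53 targets (adjusted p = 0.0048), estrogen-induced genes (15 higher, 18 lower, median -0.04, adjusted p = 0.012), hypoxia genes (adjusted p = 0.014), ATF4 targets (adjusted p = 0.019), heat shock genes (adjusted p = 0.021) and sterol genes (adjusted p = 0.047), each lower relative to other genes, were not kept with an estimated correlation (adjusted p = 0.13, 0.13, 0.27, 0.4, 0.39 and 0.22 in that order). After quantile normalization the heat shock call alone remained (adjusted p = 0.067, 0.13, 0.057, 0.14, 0.027 and 0.27). The 15612 genes called (64.2%) were 10306 higher and 5306 lower, against 5928 and 6952 after quantile normalization.

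ICI alone was compared with control to show the receptor's activity without added hormone. PDZK1 fell 15.1-fold (-3.92 ± 0.045, n = 3 and 4, adjusted p = 9.5e-25), SLC6A14 10.6-fold, the growth factor AREG 9.93-fold, PGR 4.03-fold (-2.01 ± 0.079), CXCL12 1.44-fold and MKI67 2.3-fold (-1.2 ± 0.22, 0.00014). GREB1 was -0.29 ± 0.094 (adjusted p = 0.018; 0.11 without ICI replicate 1 and 0.062 without control replicate 4), and TFF1 0.03 ± 0.14 (adjusted p = 0.92). CPB1 rose 8.53-fold, DEPP1 6.94-fold and CGA 6.63-fold. Estrogen-induced genes fell, 36 of 50 with 7 higher (37 and 7 adjusted over the list alone; median -0.59, adjusted p = 5.3e-15), including STC2 (-1.91 ± 0.054) and NPY1R (-1.89 ± 0.068). Estrogen-repressed genes rose, 15 of 24 with 3 lower (17 and 3 adjusted over the list alone; adjusted p = 5.3e-06). Replication genes (30 of 35, median -1.13, adjusted p = 1.9e-28) and mitosis genes (31 of 33, median -1.07, adjusted p = 1.2e-27) fell with none higher (32 of each adjusted over the list alone), with PRIM1 at -1.51 ± 0.032, TYMS at -1.32 ± 0.045 and TOP2A at -1.28 ± 0.05. Inflammatory genes rose, 13 of 19 (16 adjusted over the list alone; adjusted p = 3e-07), with the chemokine CCL2 at 2.01 ± 0.14. Sterol genes rose, 11 of 21 with 1 lower (adjusted p = 0.00017), with INSIG1 at 1.37 ± 0.077 and LDLR at 0.82 ± 0.049. Luminal markers (11 of 17, adjusted p = 0.0013) and metallothioneins (7 of 10, adjusted p = 0.00021) rose, while ribosome biogenesis genes (17 of 26, adjusted p = 6.2e-07), ATF4 targets (12 of 24, adjusted p = 0.0047) and interferon genes (11 of 22, adjusted p = 0.04) fell. Estimating the correlation gave adjusted p of 0.067, 0.078, 0.18, 0.31 and 0.41 for these 5 lists. In all, 8543 genes (35.1%) were called, 4255 higher and 4288 lower, and 1675 with slide, which separates these groups, as a random block.

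**Figure D4:**
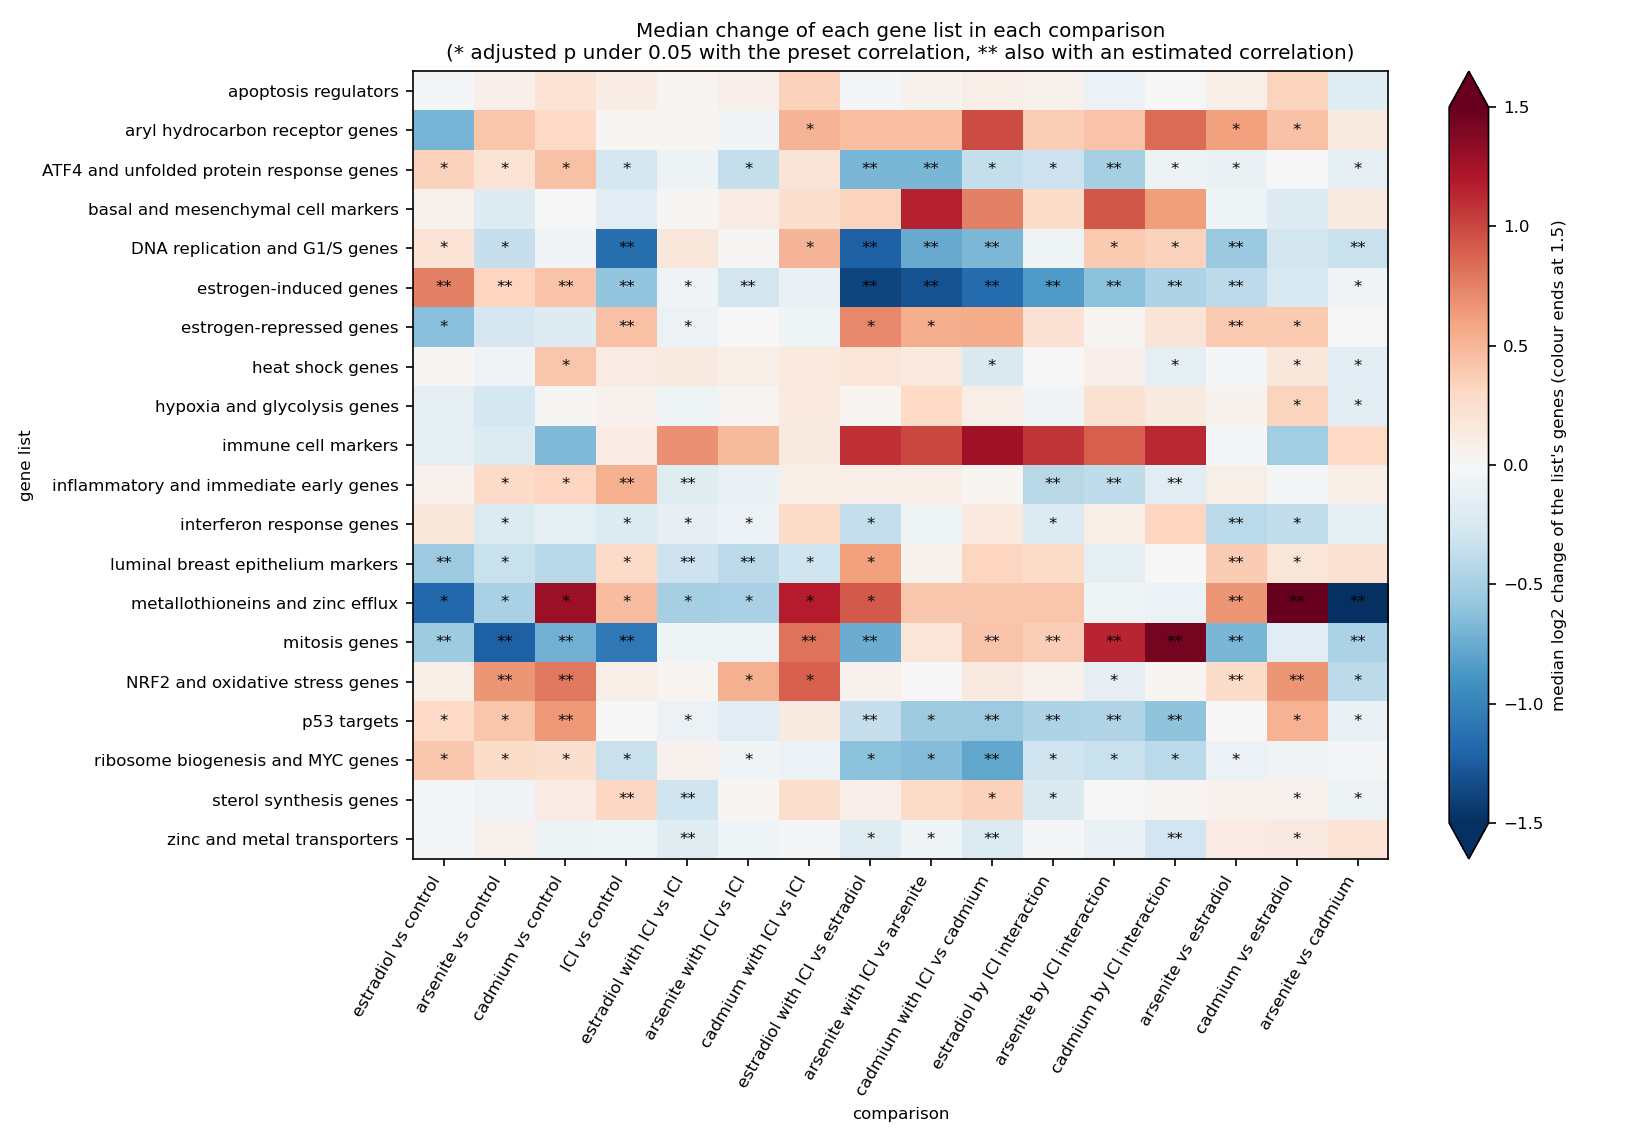
Median log2 change of each of the 20 gene lists (down the map) in the 16 comparisons (across), as colour; 1 star marks an adjusted p under 0.05 at the preset correlation, and 2 stars mark lists that also passed with the estimated correlation. Mitosis genes had medians of -1.23 with arsenite and -0.72 with cadmium, and of -0.07 and 0.81 for the same compounds in the presence of ICI.

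The compounds were then compared in the presence of ICI, to ask which changes remained when the receptor was blocked. With estradiol and with arsenite, probes with no symbol moved together, with medians of 0.54 and 0.54, against 0.07 and 0.04 for RefSeq coding genes. With cadmium their median was 0.2, against 0.19 for coding genes. A list near 0 can therefore be called lower here. Slide 4 held these groups except for 1 array, so a fixed slide block rests on estradiol with ICI replicate 1 against its other arrays. For estradiol, the change under this block is that of replicate 1 alone against the ICI arrays. Replicate 1 correlated less with its group and had a replicate probe CV of 46.7%. What the block alters can therefore come from that array and not from the slide.

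With ICI, estradiol raised PDZK1 1.9-fold (0.93 ± 0.048, n = 3 and 3), GREB1 1.3-fold (0.38 ± 0.1, adjusted p = 0.0028) and PGR 1.38-fold (0.46 ± 0.085; after quantile normalization 0.1, adjusted p = 0.47), and CXCL12 fell 2.09-fold (-1.07 ± 0.035). RNA5-8SN5 rose 13.8-fold and S100A5 12.5-fold, and MYO3A at least 6-fold. FAM177B fell 8.76-fold, MT1X 2.06-fold and HMOX1 1.71-fold. MKI67 was -0.59 ± 0.24 (adjusted p = 0.037), with adjusted p of 0.07 to 0.077 without any 1 of the ICI arrays, and it was -0.05 (adjusted p = 0.38) without estradiol with ICI replicate 1. Estrogen-induced genes were 13 higher and 18 lower of 50 (13 and 18 adjusted over the list alone; median -0.05, adjusted p = 0.0088), with CA12 at 0.69 ± 0.033 and TPD52L1 at 0.68 ± 0.035. The adjusted p was 0.12 with an estimated correlation and, with slide as a fixed block, 0.18 at a median of 0.06. Metallothioneins (7 of 10 lower, adjusted p = 0.00012), luminal markers (12 of 17 lower, adjusted p = 0.00023), sterol genes (11 of 21 lower, adjusted p = 0.00093), inflammatory genes (10 of 19 lower, adjusted p = 0.0061) and zinc and metal transporters (11 of 23 lower, adjusted p = 0.0072) fell relative to other genes. For metallothioneins the adjusted p was 0.069 with an estimated correlation, and with the slide block it was 0.092 for inflammatory genes and 0.062 for transporters. The block took the medians of these 5 lists from -0.5, -0.31, -0.3, -0.18 and -0.18 to -0.3, -0.04, -0.2, 0.06 and -0.12. Estrogen-repressed genes (adjusted p = 0.0087), p53 targets (adjusted p = 0.0095) and interferon genes (adjusted p = 0.019) were called lower as well, and with an estimated correlation the adjusted p was 0.2, 0.16 and 0.34. With the slide block it was 0.24, 0.32 and 0.54, and their medians went from -0.09, -0.09 and -0.12 to -0.02, -0.05 and 0.07. After quantile normalization the p53 and interferon calls were lost (adjusted p = 0.061 and 0.091). Mitosis genes (7 higher, 8 lower, adjusted p = 0.2) and replication genes (17 higher, 4 lower, adjusted p = 0.6) did not pass. The 14633 genes called (60.2%) were 10440 higher and 4193 lower, against 6487 and 6530 after quantile normalization, and 16124 were called without replicate 1. With only the arrays of the comparison, 6535 were called, 5047 higher and 1488 lower.

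With ICI, arsenite raised HMOX1 5.14-fold (2.36 ± 0.064, n = 3 and 3, adjusted p = 5e-17), ATP13A3-DT 15-fold and S100A5 17.4-fold, and MYO3A at least 10.8-fold. PGR (-0.11 ± 0.085, adjusted p = 0.27), GREB1 (0.07 ± 0.1, adjusted p = 0.59) and PDZK1 (0.08 ± 0.048, adjusted p = 0.14) did not pass, although PDZK1 was -0.16 and passed after quantile normalization (adjusted p = 0.0062). CXCL12 fell 2.03-fold (-1.02 ± 0.035) and TFF1 1.84-fold (-0.88 ± 0.15). MKI67 was -0.3 (adjusted p = 0.28), with levels of -0.57 to -0.49 against -0.24 to -0.2 in ICI alone, under the same pooled SE. FAM177B fell 6.31-fold, MAST1 4.75-fold and ANKRD1 at least 2.55-fold. NRF2 genes rose, 17 of 27 with 4 lower (17 and 4 adjusted over the list alone; median 0.53, adjusted p = 0.0063; adjusted p = 0.22 with an estimated correlation), with G6PD at 1.43 ± 0.038 and NQO1 at 0.95 ± 0.046. Estrogen-induced genes fell, 28 of 50 with 8 higher (28 and 8 adjusted over the list alone; median -0.28, adjusted p = 6.2e-07), among them NRIP1 (-0.73 ± 0.047), while CA12 rose by 1.17 ± 0.033. With slide as a fixed block their median was -0.08 (adjusted p = 0.0045). ATF4 targets fell, 18 of 24 with 3 higher (19 and 3 adjusted over the list alone; adjusted p = 4.2e-07; adjusted p = 0.075 with an estimated correlation), with HSPA5 at -0.65 ± 0.05. The slide block took their median from -0.36 to -0.18 (adjusted p = 0.0097). Luminal markers fell, 10 of 17 with 1 higher (adjusted p = 0.00027), a call lost after quantile normalization (adjusted p = 0.21), and the slide block took their median from -0.39 to -0.14 (adjusted p = 0.027). Metallothioneins (6 of 10 lower, adjusted p = 0.0019), interferon genes (10 of 22 lower, adjusted p = 0.0089) and ribosome biogenesis genes (10 of 26 lower, median -0.04, adjusted p = 0.029) were called lower, and with an estimated correlation the adjusted p was 0.13, 0.3 and 0.57; with a percentile over bright probes the ribosome median was 0.01. With the slide block these medians were -0.05, 0 and 0.27 (adjusted p = 0.27, 0.38 and 0.53). After quantile normalization the interferon and ribosome calls were lost (adjusted p = 0.12 and 0.42). Mitosis genes did not pass (6 higher, 12 lower, adjusted p = 0.11). The 15114 genes called (62.1%) were 10150 higher and 4964 lower, against 6711 and 6819 after quantile normalization.

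With ICI, cadmium raised HMOX1 52.2-fold (5.71 ± 0.064, n = 3 and 3), FTMT, a mitochondrial ferritin, 21.8-fold, AKR1C3 17.1-fold and AKR1C1 12.3-fold, and MT1X 2.78-fold (1.48 ± 0.062, with another probe at -2.81) and MT2A 1.75-fold. PDIA4 fell 77.8-fold, STT3A, a subunit of the glycosylation complex, 52.1-fold, and TFAP2C 46.4-fold. PDZK1 rose 1.55-fold (0.63 ± 0.048), PGR did not pass (0.09, adjusted p = 0.37), and CXCL12 fell 3-fold and TFF1 2-fold. Mitosis genes rose, 27 of 33 with 1 lower (28 and 1 adjusted over the list alone; median 0.81, adjusted p = 5.8e-07), with NDC80 at 0.81 ± 0.029, DLGAP5 at 1.57 ± 0.06 and BIRC5 at 1.22 ± 0.053. MKI67 was 0.19 (adjusted p = 0.48), with levels of -0.06 to 0.03 against -0.24 to -0.2 in ICI alone, again under the pooled SE. Replication genes rose, 21 of 35 with 5 lower (adjusted p = 0.008; adjusted p = 0.29 with an estimated correlation), with PRIM1 at 1.06 ± 0.034. NRF2 genes rose, 21 of 27 with 4 lower (21 and 4 adjusted over the list alone; median 0.9, adjusted p = 4.4e-05; adjusted p = 0.075 with an estimated correlation), with the cystine transporter SLC7A11 at 2.8 ± 0.051. Metallothioneins rose, 9 of 10 (median 1.18, adjusted p = 0.0019; adjusted p = 0.13 with an estimated correlation). Aryl hydrocarbon receptor genes rose (5 of 7, adjusted p = 0.023), with UGT1A6 at 2.24 ± 0.082, and luminal markers fell (10 of 17, adjusted p = 0.024). Estimating the correlation gave adjusted p of 0.13 and 0.19, and after quantile normalization the luminal p was 0.41. With the slide block neither passed: the receptor genes went from a median of 0.51 to 0.66 (adjusted p = 0.083) and luminal markers from -0.3 to -0.04 (adjusted p = 0.23). Estrogen-induced genes did not pass (18 higher, 22 lower, median -0.1, adjusted p = 0.29). The 16393 genes called (67.4%) were 10097 higher and 6296 lower.

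Each compound with ICI was compared with the compound alone, to measure what the antagonist removed. ICI lowered PGR 16.9-fold under estradiol (-4.08 ± 0.079, n = 3 and 4), 8.76-fold under arsenite (-3.13 ± 0.079) and 9.26-fold under cadmium (-3.21 ± 0.079), and PDZK1 23.3-fold, 24.8-fold and 28.2-fold. AREG fell 66.1-fold, 44.2-fold and 24.2-fold, and CXCL12 6.24-fold, 5-fold and 7.7-fold. GREB1 fell by 1.15, 0.76 and 0.72 (SE 0.094 each). Under estradiol, EGR3 fell at least 16.3-fold, FGFBP2 at least 32.2-fold and IL24 28.8-fold, and CGA rose 33.1-fold, TM4SF1 17.8-fold and DRAIC 15.7-fold. Under arsenite, MPPED2 fell 31.3-fold and the fatty acid elongase ELOVL2 27.9-fold, and DEPP1 rose 16.7-fold. Under cadmium, SOX3 fell 29.2-fold, and DEPP1 rose 14.5-fold. HMOX1 under ICI was 1.52-fold lower with arsenite and 1.43-fold higher with cadmium.

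Estrogen-induced genes fell in all 3 of these comparisons, 45 of 50 in each, with medians of -1.38 (adjusted p = 1.9e-27), -1.31 (adjusted p = 1.3e-27) and -1.16 (adjusted p = 1.9e-27) and with 4, 3 and 2 genes higher; examples were NRIP1 under estradiol (-2.23 ± 0.044), STC2 under arsenite (-2.75 ± 0.054) and NPY1R under cadmium (-2.56 ± 0.068). Estrogen-repressed genes rose under estradiol (18 of 24, adjusted p = 0.0033; adjusted p = 0.15 with an estimated correlation) and arsenite (16 of 24, adjusted p = 0.0063; adjusted p = 0.19 with an estimated correlation). Replication genes fell under each compound, 33, 26 and 25 of 35 (adjusted p = 1.4e-21, 1.8e-11 and 5.2e-11), with MCM2 at -1.59 ± 0.05 under estradiol and UHRF1 at -2.44 ± 0.11 under arsenite. Mitosis genes fell under estradiol (25 of 33, median -0.74, adjusted p = 1.9e-10), did not pass under arsenite (15 higher, 6 lower, adjusted p = 0.79) and rose under cadmium (22 of 33 with 1 lower, median 0.43, adjusted p = 0.0069), with HMMR at 1.25 ± 0.054. ATF4 targets fell under each compound, 18, 19 and 15 of 24 (adjusted p = 3e-10, 5.1e-11 and 5.2e-07), with ASNS at -2.21 ± 0.052 under arsenite; the call under cadmium had an adjusted p of 0.076 with an estimated correlation. The p53 targets fell, 15, 16 and 15 of 22 (adjusted p = 1.9e-05, 0.00022 and 6.2e-09; under arsenite the adjusted p was 0.051 with an estimated correlation), with FAS at -1.43 ± 0.047 under estradiol and AEN at -2.13 ± 0.08 under cadmium. Ribosome biogenesis genes fell, 20, 25 and 24 of 26 (adjusted p = 3.3e-10, 2.4e-13 and 1.2e-14; adjusted p = 0.085, 0.051 and 0.039 with an estimated correlation), with NOLC1 at -1.47 ± 0.04 under cadmium. Zinc and metal transporters fell under each compound (adjusted p = 0.046, 0.045 and 0.0003; adjusted p = 0.079, 0.079 and 0.0043 with an estimated correlation; under estradiol adjusted p = 0.056 after quantile normalization), with SLC39A10 at -2.25 ± 0.062 under cadmium. Under estradiol, interferon genes fell (14 of 22, adjusted p = 1.4e-05) and luminal markers (12 of 17, adjusted p = 0.0088) and metallothioneins (8 of 10, adjusted p = 0.0063) rose, with adjusted p of 0.079, 0.13 and 0.19 with an estimated correlation. Under cadmium, heat shock genes fell (adjusted p = 0.024) and sterol genes rose (14 of 21, adjusted p = 0.044), with adjusted p of 0.4 and 0.21 with an estimated correlation, and of 0.1 for heat shock genes after quantile normalization. The genes called were 17791, 16721 and 17676 (73.1%, 68.7% and 72.7%), with 12149, 10990 and 12242 higher; probes with no symbol had medians of 0.85, 0.75 and 0.85, and quantile normalization gave 8299, 8243 and 8881 higher. Slide and scan day separate these groups, and with slide as a random block the counts were 5601, 3188 and 4694.

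The interactions tested whether ICI altered the effect of each compound. The interaction for PGR was -2.07 log2 units for estradiol (adjusted p = 5.7e-12), -1.12 for arsenite (adjusted p = 7e-08) and -1.2 for cadmium (adjusted p = 1.5e-08), and PDZK1, GREB1 and CXCL12 had negative interactions with each compound. IL24 (-2.91 ± 0.085) and EGR3 (-2.87 ± 0.24) were among the most negative interactions for estradiol, GPNMB (-2.59 ± 0.16) for arsenite, and PDIA4 (-3.28 ± 0.066), FGFBP2 (-3.25 ± 0.4) and IFI6 (-2.76 ± 0.056) for cadmium. Among positive ones were NR0B2 for estradiol (3.49 ± 0.33), S100A5 for arsenite (3.55 ± 0.4) and TAAR8 for cadmium (4.26 ± 0.53). For HMOX1 the interaction was -1.14 for arsenite (adjusted p = 7.3e-10) and -0.03 for cadmium (adjusted p = 0.81), and for MT1X it was -0.08 for arsenite (adjusted p = 0.47) and -0.37 for cadmium (adjusted p = 0.00076).

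Estrogen-induced genes had negative interactions with each compound, 38, 41 and 34 of 50 for estradiol, arsenite and cadmium (39 for estradiol adjusted over the list alone), with medians of -0.85 (adjusted p = 1.3e-22), -0.62 (adjusted p = 6.5e-18) and -0.46 (adjusted p = 2.4e-13); FHL2 was -1.12 ± 0.058 for estradiol and the protease gene CTSD -1.18 ± 0.07 for arsenite and -1.4 ± 0.07 for cadmium. Mitosis genes had positive ones, 20, 30 and 31 of 33 with none negative, with medians of 0.37 (adjusted p = 0.00096), 1.14 (adjusted p = 3.4e-17) and 1.43 (adjusted p = 3.4e-17); NDC80 was 1.2 ± 0.038 for arsenite and 1.81 ± 0.038 for cadmium. For estradiol the mitosis call was lost with slide as a fixed block (adjusted p = 0.26), although the median there was 0.5. The p53 targets had negative interactions, 13, 15 and 13 of 22 (adjusted p = 3.3e-07, 2.4e-06 and 3.9e-09), as did inflammatory genes, 10, 11 and 8 of 19 (adjusted p = 0.0014, 0.0063 and 0.013). ATF4 targets were negative (15, 19 and 10 of 24; adjusted p = 3.5e-08, 6.9e-11 and 0.0083; adjusted p = 0.051, 0.023 and 0.34 with an estimated correlation), with DDIT3 at -1.67, -1.66 and -1.3. Ribosome biogenesis genes were negative too (14, 17 and 17 of 26; adjusted p = 4.1e-05, 7.9e-08 and 4e-10; adjusted p = 0.27, 0.15 and 0.086 with an estimated correlation). Replication genes were positive for arsenite (22 of 35, adjusted p = 0.0012) and cadmium (20 of 35, adjusted p = 0.01), with adjusted p of 0.19 and 0.31 with an estimated correlation. Zinc and metal transporters were negative for cadmium (9 of 23, adjusted p = 0.00053), as were heat shock genes (8 of 20, adjusted p = 0.0072; adjusted p = 0.32 with an estimated correlation). Interferon genes (adjusted p = 0.00052) and sterol genes (adjusted p = 0.012) were negative for estradiol and NRF2 genes (adjusted p = 0.021) for arsenite, with adjusted p of 0.16, 0.12 and 0.31 with an estimated correlation. The slide block also ended the estradiol calls of interferon and ribosome biogenesis genes (adjusted p = 0.15 and 0.17), taking their medians from -0.2 and -0.3 to 0.09 and -0.06, and took sterol genes from -0.22 to -0.1 (adjusted p = 0.05). Quantile normalization ended the calls of sterol genes for estradiol, NRF2 genes for arsenite and ATF4 targets for cadmium (adjusted p = 0.063, 0.31 and 0.097). The genes called were 13277, 12976 and 14145, of which 9520, 8731 and 10113 were positive, against 6207, 6031 and 6356 positive after quantile normalization. A shift between scan days cancels in the interactions and shifts between slides do not. With slide as a random block 2697 genes were called for arsenite and 3847 for cadmium, and after normexp and quantile normalization 8586 and 8746. Basal and mesenchymal markers, immune cell markers and apoptosis regulators passed in none of the 16 comparisons; immune markers had medians of 1.1, 1.0 and 1.26 where ICI was added to estradiol, arsenite and cadmium (adjusted p = 0.31, 0.16 and 0.33).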

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

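The tests of explanations in this part were chosen after the patterns had been seen, and their bounds were set after the values were known; the interaction tests were planned.

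The effect of each compound on estrogen-responsive genes differed between the groups without and with ICI. For arsenite and cadmium, slide cannot be told apart from ICI in this difference. With slide as a random block the interactions called went from 12976 to 2697 for arsenite and from 14145 to 3847 for cadmium. As log2 changes, the effect of estradiol on PGR went from 2.54 without ICI to 0.46 with it (difference -2.07), on GREB1 from 1.24 to 0.38 (-0.86), on PDZK1 from 1.55 to 0.93 (-0.62), on CXCL12 from 1.05 to -1.07 (-2.12) and on ESR1 from -0.9 to 0.29 (1.19). The effect of arsenite went from 1.01 to -0.11 for PGR (-1.12), from 0.53 to 0.07 for GREB1 (-0.47), from 0.8 to 0.08 for PDZK1 (-0.71), from 0.77 to -1.02 for CXCL12 (-1.8), from 0.23 to -0.88 for TFF1 (-1.11) and from -0.35 to 0.13 for ESR1 (0.47). The effect of cadmium went from 1.29 to 0.09 for PGR (-1.2), from 0.67 to 0.24 for GREB1 (-0.43), from 1.53 to 0.63 for PDZK1 (-0.9), from 0.84 to -1.58 for CXCL12 (-2.42) and from -0.33 to -1 for TFF1 (-0.68). TFF1 changes depended on the scaling, and the GREB1 difference for arsenite had an adjusted p of 0.055 after normexp and quantile normalization, as the MKI67 difference for arsenite given next had one of 0.069.

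Stress and proliferation genes differed as well. With ICI the effect of estradiol changed from -1.33 to -1.04 for MT1X (0.29), from -1.23 to -0.51 for MT2A (0.72) and from 0.14 to -0.77 for HMOX1 (-0.91). The effect of arsenite on HMOX1 went from 3.51 to 2.36 (-1.14) and on MKI67 from -1.65 to -0.3 (1.36), and that of cadmium on MT1X from 1.84 to 1.48 (-0.37) and on MKI67 from -1.69 to 0.19 (1.88). Over all genes, 13277 interactions were called for estradiol, 12976 for arsenite and 14145 for cadmium.

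Single arrays stood apart from the others in 4 of 56 groups of 4 values, by the gap to the nearest array over the whole range, where chance gives about 1 in 20. The 75th percentile of estradiol replicate 4 was 704 against 953 to 982 in the other arrays (0.896). The slope of the spike-in controls was 0.987 in control replicate 2 against 1.00 in the others (0.994). The log2 level of TFF1 was 9.07 in estradiol replicate 4 against 8.61 to 8.69 (0.842), and that of MKI67 was -0.85 in cadmium replicate 4 against -0.67 to -0.64 (0.83).

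The first pattern weighed is the shift that arsenite shared with estradiol, over the 9665 genes called in both in the same direction that had a value on every array (4541 up and 5124 down). With divided controls the lowest aligned change was still 0.473, which argues against independent error of single control arrays as its source. A deviation common to all control arrays would stay in both parts, so dividing them cannot test it. Array brightness is argued against as well, since within groups the shift had a slope of 0.01 (SE 0.023) on the log2 75th percentile. Among genes changed at least 2-fold in both, chosen on some arrays and measured on the rest, other probes of the same gene gave 0.21 of the fall (0.16 to 0.24 over 6 ways, 38 to 52 genes) and 0.41 of the rise (0.23 to 0.53, 24 to 34 genes). Probe-specific signal may therefore account for much of these shared falls, and it stays open for the rises. When genes were chosen by their other probes instead, the probe used gave 0.35 of the fall and 0.18 of the rise, so a choice by either side lowers the other. Estrogen receptor activity that ICI blocks stays open too. With coding genes chosen by estradiol against 1 part of the controls, and arsenite set against the rest, the share of the shift left with ICI was 0.56 (0.53 to 0.59 over the 6 ways to divide them), between the bounds set. For cadmium it was 0.56 (0.54 to 0.58), and for estradiol, with its own arrays divided as well, 0.37 (0.31 to 0.42). The arrays of the metals with ICI lie on another slide than ICI alone, as do 2 of the 3 arrays of estradiol with ICI. The remaining array had a shift of 0.23 where its group had 0.22, and a single array excludes nothing. Estradiol shared the slide of the controls, so the slide of the metals alone does not give a shift in common with estradiol.

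The second pattern is the positive interaction of probes with no RefSeq name, with medians of 0.76, 0.65 and 0.77 for estradiol, arsenite and cadmium. Against ICI alone these probes rose by medians of 0.54 with estradiol and with arsenite. With cadmium they had 0.2, against 0.19 for coding genes. Cadmium without ICI gave -0.7 against control, so its interaction is not mainly a rise with ICI. A single shift for slide 4, added to each compound's effect without ICI, may account for the interactions, since their medians range over 0.12. But slide 4 held those groups and nothing else. Levels on it differed, at 0.19 to 0.26 over these probes for cadmium and 0.57 to 0.64 for the other arrays. The array of estradiol with ICI on slide 3 held 0.62 of its group's rise, which would be small if the slide were the source and near 1 if it were not, and this array differed from its group in other ways. Slide and treatment cannot be told apart here. Among biological explanations, a general effect of ICI with a compound on non-coding transcripts was not tested apart from the slide.

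The third pattern is the size of single changes with cadmium and with ICI, where a gene's other probes can be compared with the one used. Genes were again chosen on some arrays and measured on the rest. For falls of at least 2-fold, the other probes gave 0.11 of the change for estradiol with ICI against ICI (-0.24 to 0.54 over 3 ways), -0.09 for arsenite with ICI (-0.12 to -0.06), 0.23 for cadmium with ICI (0.21 to 0.26) and 0.46 for cadmium against control (0.45 to 0.48 over 6 ways). Probe-specific signal may account for much of the falls with arsenite and ICI, and it stays open for the others. For rises they gave 0.58 (0.49 to 0.67), 0.73 (0.65 to 0.8), 0.5 (0.46 to 0.53) and 0.51 (0.44 to 0.57) in the same order. This argues against it only for the genes so chosen with arsenite and ICI, and leaves the others open. When genes were chosen by their other probes on all arrays, the probe used gave 0.21, 0.2, 0.39 and 0.47 of the rises. For the falls it gave 0.07, 0.33, 0.07 and 0.31. The shares therefore depend on which probes choose the genes. With all arrays, the genes with another probe numbered 106, 38, 284 and 298 for the falls.

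Low shares were not limited to those comparisons. They were 0.27 for falls with estradiol against control, 0.42 and 0.49 for falls and rises with arsenite, 0.2 for rises with cadmium against estradiol, 0.2 and 0.41 for falls and rises with arsenite against cadmium, and 0.35 for negative interactions with cadmium. With ICI alone they were 0.85 for falls and 0.78 for rises.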

How the results depend on the processing

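Every alternative below was planned before the data were examined except the 75th percentile over bright probes, which kept every count of called genes within 1.5 times. Leaving out any 1 array, quantile normalization, the series table, the replicate block and all probes kept each count of called genes within 1.5 times. A minimum of 1.5-fold lowered the counts by its construction, to 5730 genes for estradiol, 5376 for arsenite, 10387 for cadmium, 2517 for ICI, 7701, 8204 and 10271 for estradiol, arsenite and cadmium with ICI against ICI, 11315, 9893 and 10976 for the same against the compound alone, 8345, 8201 and 9308 for the interactions, 1735 for arsenite against estradiol, 7994 for cadmium against estradiol and 7780 for arsenite against cadmium. With slide as a random block the counts were 1540 for arsenite, 4597 for cadmium, 1675 for ICI, 5601, 3188 and 4694 with ICI against the compound alone, 2697 and 3847 for the arsenite and cadmium interactions, 303 for arsenite against estradiol and 2639 for cadmium against estradiol; genes shared with estradiol were 1467 and 3738, the arsenite covariance 0.245, and the aligned changes 0.45 and 0.556. This block lowers counts by its construction, since it takes arrays of one slide as correlated and most groups lay on a single slide. Normexp with quantile normalization gave 8586 and 8746 for the arsenite and cadmium interactions, 4541 for arsenite against estradiol and 10367 for cadmium against estradiol, covariances of 0.109 and 0.135 and aligned changes of 0.392 and 0.469. With only the arrays of the comparison, estradiol with ICI against ICI gave 6535 genes. Without the filter on dim probes the covariances were 0.176 and 0.241 and the aligned changes 0.46 and 0.627. With all probes the arsenite covariance was 0.254 and the aligned changes 0.503 and 0.567. After quantile normalization the covariances were 0.232 and 0.281 and the aligned changes 0.475 and 0.561. In a fit to the arrays of 1 scan day alone, which adjusts for nothing, the aligned changes were 0.453 and 0.555. Leaving out 1 array moved the arsenite aligned change between 0.484 and 0.508 and its covariance between 0.231 and 0.244, and those of cadmium between 0.595 and 0.633 and between 0.286 and 0.306. Where no construction is named, the cause was not tested.

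Of the 320 gene list results, an estimated correlation ended 82 and left 238 as they were, quantile normalization ended 21 and added 12, and the replicate block added 2. The number of comparisons in which a list passed became 0 of 3 for aryl hydrocarbon receptor genes, 3 of 13 for ATF4 targets, 6 of 11 for replication genes, 2 of 7 for estrogen-repressed genes, 0 of 5 for heat shock genes, 0 of 2 for hypoxia genes, 1 of 8 for interferon genes, 4 of 9 for luminal markers, 3 of 11 for metallothioneins, 4 of 8 for NRF2 genes, 6 of 12 for p53 targets, 1 of 12 for ribosome biogenesis genes, 2 of 6 for sterol genes and 3 of 6 for zinc and metal transporters; after quantile normalization heat shock genes passed in 3, and with the replicate block apoptosis regulators passed in 2. With the estimated correlation, estrogen-induced genes passed in 12 of 14, inflammatory genes in 5 of 7 and mitosis genes in 12 of 12. Of 468 single-gene results, 4 reversed under quantile normalization and 2 under normexp: TFF1 for cadmium against control (0.48 and 0.43), cadmium against estradiol (0 after quantile) and arsenite against cadmium (-0.05 after quantile, 0 after normexp), and PDZK1 for arsenite with ICI against ICI (-0.16 after quantile). The MKI67 interaction with estradiol, -0.21 with all arrays, lay between -0.48 and 0.33 when 1 array was left out, and was 0.33 without estradiol with ICI replicate 1. Leaving out 1 array otherwise weakened single-gene results in 68 cases, strengthened them in 6 and left 3915 as they were, and the replicate block weakened 3, among them HMOX1 for estradiol (adjusted p = 0.053); the series table changed none of 468. Slide could be fitted as a fixed effect for estradiol against control, arsenite against cadmium, the compounds with ICI against ICI and the estradiol interaction. In the last 4 of these it rests on estradiol with ICI, the single group on more than 1 slide, and so on its discordant replicate 1. Elsewhere it could not be fitted, nor could scan day across days. Dim probes limit depth: 12688 were removed, and 55.1% to 72.7% of spots per array were well above background.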

Other observations

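The set of genes in the next paragraph and the tests of regrouped arrays were chosen or read after the main comparisons had been seen.

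A wider set of estradiol-responsive genes was examined beyond the lists. Among 300 genes that estradiol raised at least 2-fold and that were at least 2-fold lower with estradiol and ICI, arsenite raised 223 and lowered 4 (median 0.8) and cadmium raised 222 and lowered 8 (median 0.84). ICI alone lowered 174 and raised 16 (median -0.57). In the presence of ICI, arsenite raised 106 and lowered 58 (median 0.14), cadmium raised 141 and lowered 53 (0.31), and estradiol raised 113 and lowered 35 (0.26). The interactions were negative for 155 of these genes and positive for 15 with arsenite (median -0.62), and negative for 145 and positive for 18 with cadmium (-0.5). Since the set was chosen by the estradiol response, its changes with estradiol are not evidence of anything further. It was chosen with the same control arrays that the metals were compared with, which by itself raises the counts of genes higher with a metal, and the interactions share arrays with its selection too. No value for unchanged groups was computed for this set, so these counts do not measure a shared effect.

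Likeness to estradiol was also measured among the groups with ICI, where slides and groups overlap. Genes called for estradiol with ICI against ICI moved in the same direction by 0.751 with arsenite (0.713 to 0.781 over the ways to divide the ICI arrays) and by 0.441 with cadmium (0.409 to 0.464). With the ICI arrays shared, 10984 genes were called in the same direction and 275 in opposite ones for arsenite, and 7666 and 2873 for cadmium. Probes with no symbol, with medians of 0.54, 0.54 and 0.2 for estradiol, arsenite and cadmium, enter these values. Their part was not taken out.

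The arrays of each comparison were also regrouped, counting the splits with as many called genes as the real one, the real one included. For estradiol, arsenite and cadmium against control that was 1 of 35 splits, the smallest share possible. The real split had 13227, 12942 and 17227 genes, and another had at most 218, 5 and 54. For ICI against control it was 1 of 35, with 8543 genes against at most 5161. For the compounds with ICI against the compound alone it was 1 of 35 each, with 17791, 16721 and 17676 genes against at most 14747, 12804 and 14541. In these 4 comparisons the highest other split kept the 3 ICI arrays together and moved 1 array beside them, so its count follows the structure of the samples. Regrouping shows only that the arrays of a group resemble each other more than those of the other group. It cannot tell treatment from slide where the groups lay on different slides. If the replicates are technical, it cannot exclude chance differences between cultures either. For arsenite against estradiol, cadmium against estradiol and arsenite against cadmium it was 1 of 35, with 7078, 15869 and 15612 genes against at most 3, 51 and 3. For the interactions, 1 of 100 drawn splits gave as many, with 13277, 12976 and 14145 genes against at most 8731, 8785 and 10265. For the compounds with ICI against ICI the 10 possible splits are too few for a share under 0.05; the real counts were 14633, 15114 and 16393, against at most 4440, 1 and 2.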
